A study of Mus musculus with 14 samples.

How the data were processed

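Chromatin immunoprecipitation with sequencing was applied to ATDC5, a mouse teratocarcinoma-derived line that forms cartilage-like nodules in culture. Per the labels' protocols, cells were spotted as dense droplets and differentiated with β-glycerophosphate and an ascorbate, and chromatin was taken on days 0, 3 and 10. Formaldehyde-fixed, sonicated chromatin was precipitated with an antibody against H3K4me3, a histone mark of active and poised promoters, or against RUNX2, a runt-domain transcription factor required for osteoblast and hypertrophic chondrocyte differentiation. Each of the 2 antibodies was used on each of the 3 days in 2 libraries, numbered 1 and 2 in the labels. Of the 14 samples, 12 had a peak list. The 2 input libraries, and the SOX9 and non-specific antibodies that the protocol mentions, were not analysed here. Nothing in the labels says that the libraries of a day came from separate cultures, so the spread between them may be technical.

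Per the submitters' processing notes, FastQC, Trim Galore, HISAT2 2.2.0 and MACS2 were used on reads of 75 bp. The settings, the removal of duplicate reads, the use of the input libraries as a control and the other versions are not given in the sources used here. HISAT2 can split reads across introns, and whether that was turned off is not given either. Each deposited list carries the name of a single library, so peaks were called per library. Per the column order of the narrowPeak format, the deposited lists give each peak's start, end and summit, a score, the fold enrichment at the summit as a linear ratio to the caller's local background, and the −log10 of its p-value and q-value. The score was checked to be 10 times the −log10 q, without its decimals. The smallest −log10 q in a list lay between 1.30 and 1.63, which puts the authors' limit at a q of 0.05. Fold enrichment, score and −log10 q are the authors' values and were used only to describe, rank or filter peaks within a list, because each depends on the depth and background of its own library. The number of reads per library is unknown here. A gene without a peak therefore had none called at its library's depth, which does not show that the mark was absent. A narrow-peak caller also divides wide H3K4me3 domains, so that the number of peaks is not the number of domains.

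The submitters' notes name the build GRCm39. The coordinates in the lists were not compared with genes of that build, but they matched a RefSeq table of GRCm38. Of the summits of the H3K4me3 lists, 37.9 to 70.2% lay within 1 kb of an end of a protein-coding gene of that table. After the table had been shifted by 20 kb, 6.12 to 7.99% did. The lists were therefore read as GRCm38, and every position printed is a peak position from the lists, counted from 1. The table gives gene spans and no strand or transcript starts. The planned promoter, 1 kb either side of a transcript start, was for this reason replaced by 1 kb either side of either end of the gene span. Below, "gene end" means the first or last base of the span of a protein-coding gene, unless all annotated genes are named. A peak at the 3′ end of a gene counts as well. The planned search for the RUNX motif at summits needs a genome sequence and was not run.

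Overlapping lines of a list were merged, and peaks on assembled chromosomes were used. A gene was called marked on a day when both libraries had a peak overlapping one of its windows by at least 1 bp. It had gained a peak between 2 days when neither library of the earlier day and both of the later day had one, and lost a peak in the opposite case. No test was made per gene, because an exact permutation of 2 against 2 libraries could not pass 0.05. The count was set beside the same count for the 2 crosswise splits of the 4 libraries, each of which pairs a library of one day with a library of the other. All 21887 protein-coding genes on assembled chromosomes were examined. A further 23 gene lists, with 642 entries for 600 distinct genes, had been fixed for chondrocyte, osteoblast and other cell types, signalling pathways and general cell functions. All their symbols were found in the table. Each list was tested with a two-sided Fisher's exact test against the genes that could have changed, with Benjamini-Hochberg adjustment over 138 tests for H3K4me3 and 46 for RUNX2 and a threshold of 0.05. Genes are the units of these tests and were treated as independent, so their p values do not measure the spread between libraries. Reproducible RUNX2 regions were stretches with a peak in both libraries of a day. Their overlap with H3K4me3 was compared with 1000 random placements on the same chromosomes. Shares of regions carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat regions as independent. Numbers of peaks were compared with a two-sided exact permutation test, whose smallest possible p for 2 against 2 libraries is 0.333, so that no such comparison could pass 0.05.

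These tests, the gene lists, most of the alternatives and the rule for named genes were set before the data were examined, except for the change from transcript starts to gene ends and the alternatives said below to have been chosen later. The rule named, for each comparison and direction, up to 4 genes per list and 10 further genes genome-wide, in the order of the worse of the 2 within-list ranks of the peak by −log10 q. Predicted genes were passed over among the 10. A gene that the rule names among the losses from day 3 to day 10 is not reported here. For RUNX2 it named up to 4 members per list and the 10 top regions of each day, and it always named Runx2, Sox9, Col2a1, Acan, Col10a1, Mmp13, Ihh, Sp7, Spp1, Alpl, Bglap and Ibsp. Alternatives were a −log10 q of at least 5, windows of 500 and 2500 bp, an overlap of at least 200 bp or 50% in both directions, equal numbers of top peaks in each list, all 49943 annotated genes, all sequences, covered length in place of number, a block for the replicate number, and each library left out in turn.

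The calling of gains and the list test were tested on simulated data in which peaks were given to 200 genes and 5% of peaks were dropped at random. All of the seeded genes, 100%, were recovered in each of the 3 comparisons of days, with 1 further gene called for days 0 and 3, 2 for days 3 and 10 and 28 for days 0 and 10. Recovery was fixed in advance, because the seeded peaks were added to both later libraries after the drop, so it checks the code only. The drop of 5% does not mimic the real difference between replicates, such as 13765 and 20863 peaks on day 0. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.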

Results

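H3K4me3 and RUNX2 were mapped in ATDC5 cells on days 0, 3 and 10 of chondrogenic differentiation, with 2 libraries per antibody and day. The series is titled for the regulation of genes by RUNX2 in mature chondrocytes, and its design sets the 2 antibodies beside each other at 3 time points. The H3K4me3 lists held 13765 and 20863 peaks on day 0, 28653 and 26781 on day 3 and 15219 and 29022 on day 10. The RUNX2 lists held 108 and 102 peaks on day 0, 19319 and 16859 on day 3 and 101 and 97 on day 10. Protein-coding genes with an H3K4me3 peak at a gene end in both libraries numbered 10372 on day 0, 12088 on day 3 and 11314 on day 10, and 10322 genes were marked in all 6 lists.

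**Figure D1:**
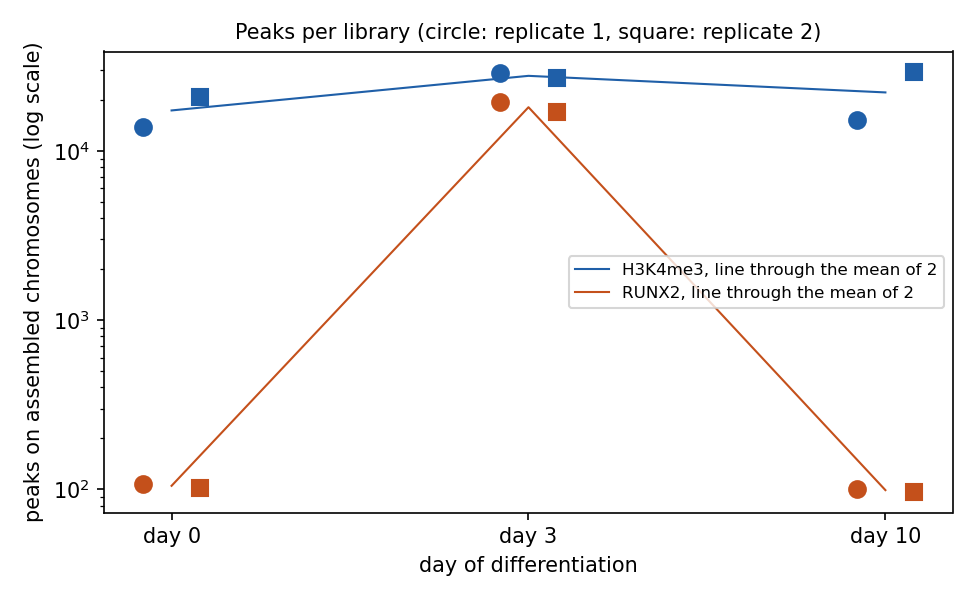
Number of peaks on assembled chromosomes (log axis) in each of the 12 lists by day of differentiation, with H3K4me3 in blue, RUNX2 in orange, circles for replicate 1, squares for replicate 2 and lines through the mean of the 2. The RUNX2 lists rise from 108 and 102 peaks to 19319 and 16859 on day 3 and are back at 101 and 97 on day 10, while the H3K4me3 lists lie between 13765 and 29022.

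The chondrocyte genes named in advance showed different histories. Runx2 itself, Sox9, the master transcription factor of chondrocytes, Col2a1, which encodes the main cartilage collagen, Sp7, an osteoblast transcription factor, and Alpl, which encodes the phosphatase needed for mineralisation, had an H3K4me3 peak in all 6 lists. The Col2a1 peaks of day 0 were weak (−log10 q of 5.45 in replicate 1 and 3.75 in replicate 2) and did not overlap each other. Acan, encoding the proteoglycan aggrecan, Spp1, encoding osteopontin, and Ihh, the hedgehog ligand of prehypertrophic chondrocytes, had none on day 0 and a peak in both libraries on days 3 and 10. Ibsp, encoding bone sialoprotein, had a peak on day 10 only, in both libraries. Col10a1, the collagen gene of hypertrophic chondrocytes, and Bglap, encoding osteocalcin, had one only in replicate 2 of day 10 (fold enrichments of 5.69 and 3.92). Mmp13, the collagenase gene of late hypertrophy, had none in any list.

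**Figure D2:**
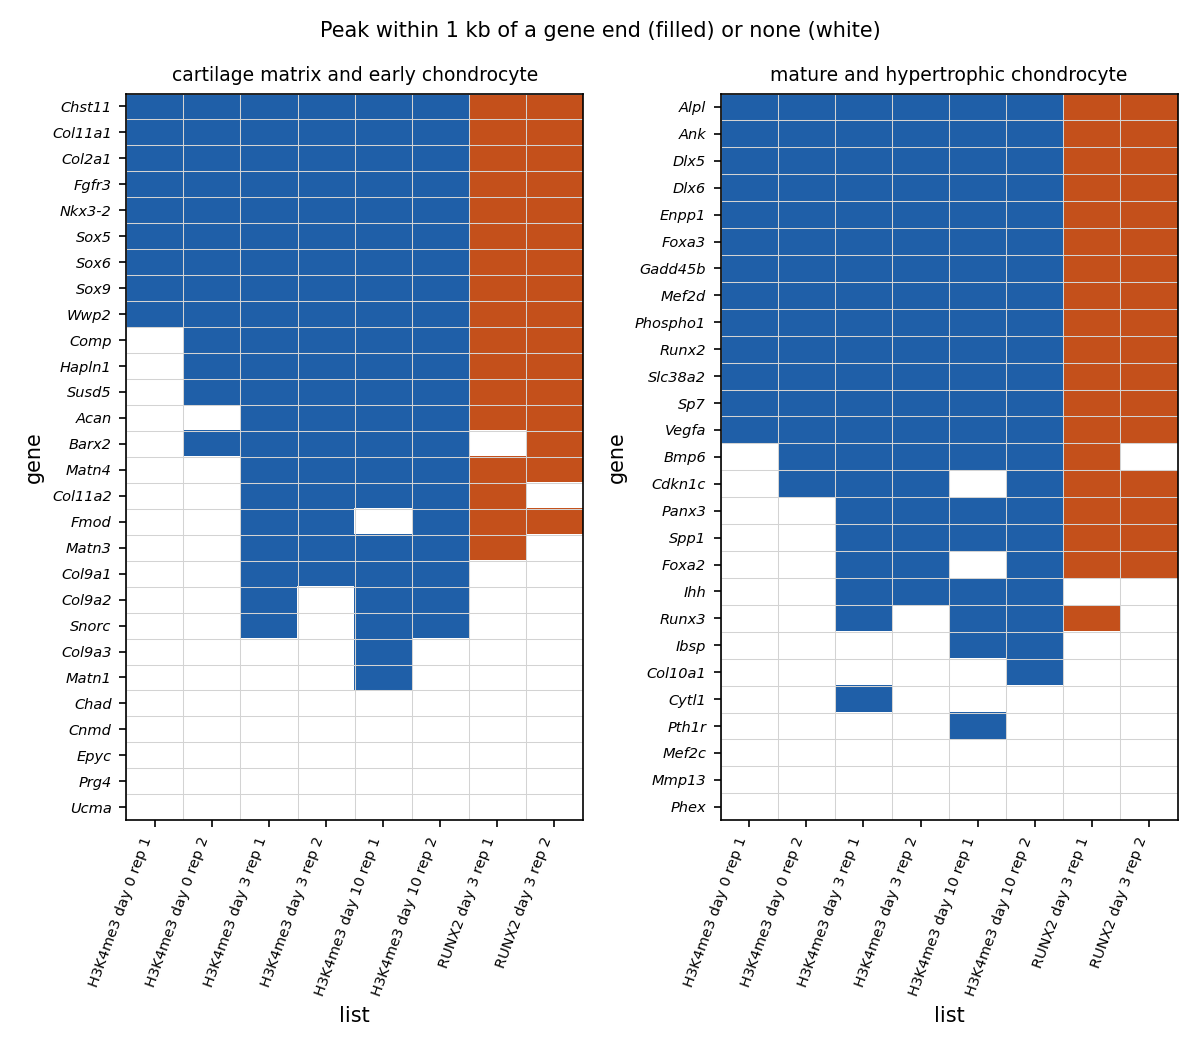
Peaks within 1 kb of a gene end (blue for H3K4me3, orange for RUNX2, white for none) of each gene of the cartilage matrix list and the mature chondrocyte list in the 6 H3K4me3 lists and the 2 RUNX2 lists of day 3. Acan, Matn4, Spp1 and Panx3 are white on day 0 and filled in all later lists shown.

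From day 0 to day 3, H3K4me3 peaks appeared at genes of the cartilage matrix. Of 15 list members without a peak in either day 0 library, 6 gained one: Acan, Matn4 and Matn3, which encode matrilins, Fmod, encoding the collagen-binding fibromodulin, and the minor collagen genes Col11a2 and Col9a1. At Acan the peak covered chromosome 7 from 79051951 to 79057194 in replicate 1 of day 3 (fold enrichment 15.9) and from 79052373 to 79056299 in replicate 2 (8.33). At Matn4 it lay on chromosome 2 from 164389322 to 164390015, with fold enrichments of 20.4 and 6.43 in the 2 libraries. The odds of a gain were 11.6 times those of the other genes that could gain one (Fisher's exact test, adjusted p = 0.00398). The call was lost when equal numbers of top peaks were compared (3 of 18 members, odds ratio 8.49, Fisher's exact test, adjusted p = 0.192). Over the 12 alternatives the adjusted p lay between 0.000399 and 0.192 and the odds ratio between 6.51, without replicate 2 of day 0, and 13.4.

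Genes of mature and hypertrophic chondrocytes were next, with 4 of 12 members gaining a peak (odds ratio 8.67, Fisher's exact test, adjusted p = 0.0626, above the threshold). These were Spp1, Panx3, encoding a channel protein of prehypertrophic chondrocytes, Foxa2, a transcription factor of hypertrophy, and Ihh. The Spp1 peak lay on chromosome 5 from 104434735 to 104436991, with fold enrichments of 16.2 and 6.89. The Ihh peaks were weak, at 5.45 and 4.28 (chromosome 1, 74951198 to 74951557 and 74950456 to 74951139), and a second peak of replicate 2, from 74951369 to 74951687, overlapped that of replicate 1. The hedgehog list gained Ihh and Hhip, which encodes a hedgehog-binding inhibitor (2 of 3 members, Fisher's exact test, adjusted p = 0.0998). The limb patterning list gained Dlx3, Tbx15, Pitx1 and Barx1 (4 of 14, Fisher's exact test, adjusted p = 0.0884), and the cell cycle list gained the D-type cyclin genes Ccnd2 and Ccnd3 (2 of 3, adjusted p = 0.0998). None of these 3 lists passed the threshold.

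**Figure D3:**
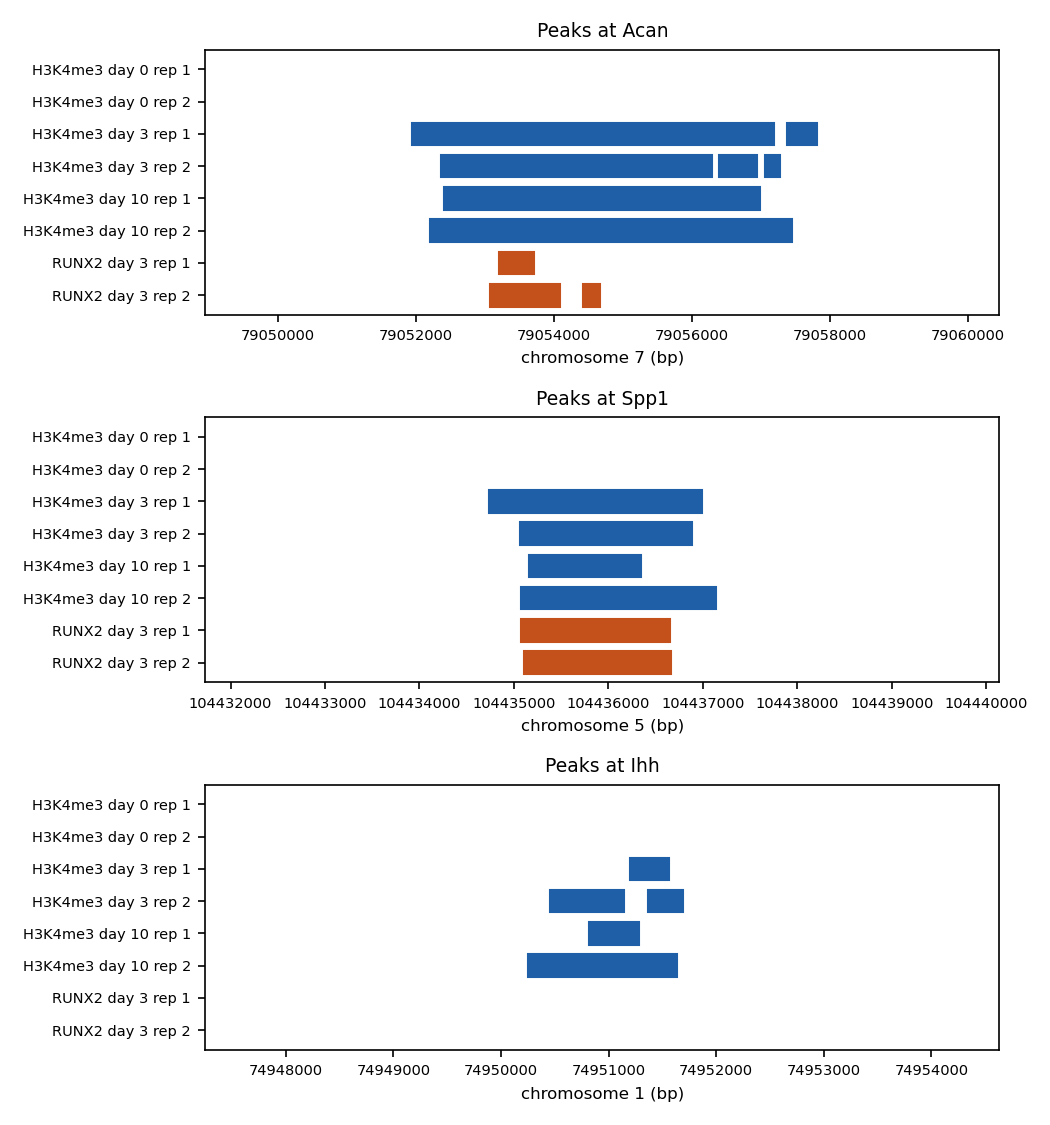
Peaks of the 6 H3K4me3 lists (blue) and the 2 RUNX2 lists of day 3 (orange) along 3 regions, with the position on the chromosome in bp on each horizontal axis. No H3K4me3 peak is drawn at Acan, Spp1 or Ihh on day 0, and the RUNX2 peaks of day 3 lie within the H3K4me3 peaks of that day at Acan and Spp1, with none at Ihh.

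Other lists gained single members or pairs between day 0 and day 3. The WNT list gained Sfrp4, encoding a secreted WNT inhibitor, and Lgr6, encoding an R-spondin receptor, and the growth factor list gained Fgf10 and Pdgfra (each adjusted p at least 0.498). Bmp3 and Dlx3 were gained in the osteoblast list, Hdac4, encoding a deacetylase that restrains RUNX2 in chondrocytes, among RUNX partners, Gdf5, a joint-forming ligand, in the BMP list, Plod2, a collagen lysyl hydroxylase, in the collagen processing list and Adm, encoding adrenomedullin, in the hypoxia list. Lists for other cell types gained Egr2 and Pdgfra (tendon and fibroblast), Erg and Sox18 (endothelial), Lipe (adipocyte), Cd68 and Cd4 (haematopoietic) and Cldn7 (epithelial). The last 3 share their window with a neighbour: the summit of replicate 1 lay nearest to Mpdu1 for Cd68, to Gpr162 for Cd4 and to Elp5 for Cldn7. The skeletal muscle, neuronal and pluripotency lists gained none of their 18, 13 and 18 unmarked members. Matrix proteases (0 of 6) and housekeeping genes (0 of 1) gained none either, and the textbook RUNX2 targets gained Spp1 and Ihh only (2 of 10, Fisher's exact test, adjusted p = 0.633). At Col11a2, Foxa2, Plod2, Ccnd2, Pdgfra, Pitx1, Egr2 and Erg the summit of replicate 1 lay 1172 to 3179 bp from the gene end, outside the window that the peak's flank reached.

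In all, 560 genes gained an H3K4me3 peak at 540 distinct peaks and 0 lost one between days 0 and 3, while the larger of the crosswise splits gave 49. With equal numbers of top peaks 254 genes gained a peak and 24 lost one, against 84 for the larger crosswise split. The 10 best-ranked genes genome-wide were Septin11, Hoxa9, Fkbp14, Rab21, Rasal3, Nup210, Mea1, Plxnb1, Smn1 and Vpreb1. In 6 of them the summit of replicate 1 lay 1405 to 2277 bp from the gene end, so that only the flank of the peak reached the window, and for Fkbp14, Rasal3, Mea1 and Vpreb1 the nearest gene end was that of Plekha8, Wiz, Klhdc3 and Top3b. None of the 10 was called with windows of 2500 bp. Of the 3118 H3K4me3 regions gained, 2613 lay over 1 kb from any end of a protein-coding gene, inside such genes or between them, as did 30971 of all 42397 regions. The number of peaks per list was 17314 ± 5019 (SD, n = 2) on day 0 and 27717 ± 1324 on day 3, a log2 ratio of 0.68 with both day 3 lists longer than both day 0 lists (exact permutation p = 0.333, the smallest possible). Leaving out replicate 2 of day 0 raised the gained genes to 1677, and leaving out replicate 2 of day 3 raised them to 932.

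From day 3 to day 10, H3K4me3 peaks appeared at few genes, among them Ibsp, a gene of mineralising cells, Dkk1, encoding a secreted WNT inhibitor, Car9, a hypoxia-induced carbonic anhydrase gene, and Col24a1, a fibrillar collagen gene. The Ibsp peak lay on chromosome 5 from 104299497 to 104299881 in replicate 1 of day 10 and from 104299408 to 104300516 in replicate 2, with fold enrichments of 2.60 and 4.18. Further genes gaining a peak were Zfp385c, Eps8l2 and its neighbour Deaf1 at the same peak, Rab17, Fxyd1, Etl4, Adgrf5, Kcns1 and Cd247. Peaks were lost at Bmp3, Wnt1, the pluripotency gene Sall4, the epithelial transcription factor gene Tfap2a, Sp6 and Neurod2. Peaks were also lost at Fkbp14, Mea1, Pin1rt1, Odf3l2 and H1f6, where the summit lay nearest to another gene, and at Fam120c and Ptcra. For Wnt1 and Tfap2a the peaks that counted in the 2 day 3 libraries lay near opposite ends of the gene.

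In all, 16 genes gained a peak and 95 lost one, fewer than the 181 of the larger crosswise split, so that the change between days 3 and 10 was not larger than the difference between libraries. Of the 13 genes named as gaining a peak, 0 were called with equal numbers of top peaks and 5 with a −log10 q of at least 5. No list passed the threshold. The smallest adjusted p values were 0.0884 for the hypoxia list (Car9, 1 of 3 members) and 0.0998 for the WNT list (Dkk1, 1 of 5). The mean number of peaks fell by 0.33 on the log2 scale, to 22121 ± 9760 (SD, n = 2) on day 10, with overlapping lists (exact permutation p = 1). Replicates 1 and 2 of day 10 differed more than the days did, with 15219 and 29022 peaks. Without replicate 1 of day 10, 194 genes gained a peak and the log2 ratio became 0.0664, and without replicate 2, 828 genes lost one.

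Across the whole course, from day 0 to day 10, the cartilage matrix and mature chondrocyte lists had the smallest adjusted p values among the gains. These p values treat genes as independent and do not measure the difference between libraries. Of 15 unmarked cartilage matrix genes 7 gained a peak, namely Acan, Matn3, Matn4, Col11a2, Col9a1, Col9a2 and Snorc, the last encoding a small chondrocyte proteoglycan (odds ratio 37.6, Fisher's exact test, adjusted p = 2.67e-06). Of 12 mature chondrocyte genes 5 did so: Spp1, Panx3, Ihh, Ibsp and Runx3, which encodes a relative of RUNX2 (odds ratio 30.4, Fisher's exact test, adjusted p = 0.000322). The Ibsp peak was weak in replicate 1 of day 10 (−log10 q of 2.67). Of the hypertrophy genes named in advance, Col10a1 had a peak only in replicate 2 of day 10 and Mmp13 had none. The textbook RUNX2 targets gained Spp1, Ihh and Ibsp (3 of 10, Fisher's exact test, adjusted p = 0.0371), and the WNT list gained Sfrp4, Lgr6 and Dkk1 (3 of 8, adjusted p = 0.0224). Spp1, Ihh and Ibsp are also among the mature chondrocyte genes just named, so the RUNX2 target list is not separate evidence. Ihh and Ibsp had no RUNX2 peak in any RUNX2 list. The Runx3 peak lay on chromosome 4 from 135120996 to 135121863 in replicate 1 of day 10, with fold enrichments of 6.51 and 6.26 in the 2 libraries. Adm and Car9 of the hypoxia list (Fisher's exact test, adjusted p = 0.0626), Dlx3, and Erg and Sox18 of the endothelial list were also gained.

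The best-ranked gains genome-wide were Wscd2, Zfp879, Rasal3, Dnaaf4, Plxnb1, Col27a1, a cartilage-expressed collagen gene, Prickle3, Zfp239, Smpdl3a and Spon2. The summit at Zfp879 lay nearest to Zfp354c. Altogether 239 genes gained a peak and 0 lost one, but the larger crosswise split gave 424, so the count alone did not exceed the difference between libraries. With equal numbers of top peaks it did (214 gained and 16 lost, against 91). No list test of a crosswise split is reported here, so a split of the libraries could also favour some lists. The cartilage matrix call held in all 12 alternatives (adjusted p between 2.45e-09 and 0.0243). Its odds ratio fell to 12.1 without replicate 1 of day 10 and 15.3 without replicate 2 of day 0, and rose to 59.2 without replicate 2 of day 10. That of the mature chondrocyte list fell to 14.8 without replicate 1 of day 10 and to 8.31 without replicate 2 of day 0. With equal numbers the mature chondrocyte list had an adjusted p of 0.382 and the WNT and RUNX2 target lists one of 1, and with a −log10 q of at least 5 these 3 lists were also lost, at 0.192, 0.661 and 1. Without replicate 2 of day 0 the RUNX2 target list had 0.129. Over the 12 alternatives the 3 lists ranged from 1.25e-05 to 0.382, from 0.00254 to 1 and from 0.0198 to 1. Mean peak numbers differed by 0.35 on the log2 scale, with overlapping lists (exact permutation p = 0.667, n = 2).

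Of the genes unmarked on day 0, 190 gained a peak on day 3 and kept it on day 10, 64 had one in both libraries on day 3 and in neither on day 10, and 15 had one on day 10 only. The 6 H3K4me3 lists also differed in a way the days do not explain. Replicate 1 of day 0 and replicate 1 of day 10 were the shortest lists and had the longest shortest peaks, 295 and 245 bp against 214 to 225 bp in the other 4, a value that follows the fragment length the caller estimates. Among those other 4 libraries, which leave a single library on days 0 and 10, 602 genes gained and 59 lost a peak from day 0 to day 3, 194 gained and 99 lost one from day 3 to day 10, and 938 gained and 110 lost one from day 0 to day 10.

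RUNX2 peaks went from almost none near genes on day 0 to over 10000 gene ends on day 3. On day 0 only 2 protein-coding genes had a RUNX2 peak at a gene end in either library, and on day 3 there were 11727 and 11688. The 2 libraries of day 3 shared 15899 reproducible regions with a median width of 1300 bp, 65.8% of them within 1 kb of a gene end. Of the genes named in advance, Runx2, Sox9, Col2a1, Acan, Sp7, Spp1 and Alpl had a RUNX2 peak at a gene end in both day 3 libraries, and Ihh, Col10a1, Mmp13, Bglap and Ibsp in neither. The Runx2 peak lay on chromosome 17 from 44813232 to 44814788 in replicate 1, with fold enrichments of 5.89 and 6.31 in the 2 libraries. Those of Sox9 reached 3.59 and 14.4 and those of Sp7 3.37 and 16.9, while Acan had 3.69 and 5.20. The number of peaks rose from 105 ± 4.24 (SD, n = 2) to 18089 ± 1739, a log2 ratio of 7.43 (exact permutation p = 0.333, the smallest possible).

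By list, RUNX2 peaks on day 3 were frequent at genes used by many cell types. They were found at 38 of 42 cell cycle genes, among them Ccnb1 and Cdk4, at 29 of 30 housekeeping genes such as Rplp0, and at 23 of 26 hypoxia and glycolysis genes such as Tpi1. They were also found at 26 of 29 genes of collagen processing, such as Crtap and Plod3, and at 25 of 30 RUNX partners, such as Smurf1, Kat6a and Cbfb (adjusted p between 3.05e-06 and 0.00212, Fisher's exact test against all protein-coding genes). The hedgehog list (17 of 20, with Ptch1 and Smo), the growth factor list (31 of 41, with Fgfr3), the WNT list (32 of 44, with Lrp5) and the BMP list (29 of 41, with Smad1) also passed. RUNX2 peaks were less frequent in the lists for skeletal muscle (1 of 20), pluripotency (4 of 23), blood (4 of 23), epithelium (5 of 21) and neurons (5 of 21), the last without a difference when each region was given to its nearest gene (8 of 21, Fisher's exact test, adjusted p = 0.261). Cartilage matrix genes (15 of 28, odds ratio 1.03, Fisher's exact test, adjusted p = 1), mature chondrocyte genes (17 of 27, adjusted p = 0.421), osteoblast genes (10 of 22, adjusted p = 0.621) and textbook RUNX2 targets (16 of 25, adjusted p = 0.419) did not differ detectably from other genes. Matrix proteases (20 of 27, Fisher's exact test, adjusted p = 0.0541), limb patterning (20 of 40, adjusted p = 0.824), tendon (12 of 25), adipocyte (9 of 20) and endothelial genes (5 of 17) did not pass either.

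With each list also tested by each region's nearest gene within 50 kb, 27 of 46 tests passed. Against genes marked by H3K4me3 on day 3, only 1 of the 46 did: RUNX2 was less frequent at limb patterning genes (20 of 30 marked members, odds ratio 0.0981, Fisher's exact test, adjusted p = 3.15e-05), with none called in both libraries at Prrx1, Pitx1, Barx1, Tbx15 or Hand2. The difference was absent when each region was given to its nearest gene (26 of 30, odds ratio 0.878, Fisher's exact test, adjusted p = 0.916) and did not pass against genes matched on H3K4me3 rank (23.9 expected, permutation test, adjusted p = 0.408), a test chosen after the result was seen. The 10 top-ranked regions of day 3 lay on chromosomes 8 and 17, with predicted or unnamed genes nearest to them, and at Ints1 (chromosome 5, 139774679 to 139775791) and Htt (chromosome 5, 34760874 to 34763015).

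From day 3 to day 10 the RUNX2 peaks at genes were no longer called. The peaks at Runx2, Sox9, Col2a1, Acan, Sp7, Spp1 and Alpl were absent from both day 10 lists, and again 2 genes had a peak at a gene end. The number of peaks fell by 7.51 on the log2 scale to 99 ± 2.83 (SD, n = 2; exact permutation p = 0.333, the smallest possible). Days 0 and 10 held 86 and 81 reproducible regions, and 73 of the 86 were shared with day 10. Of these regions 58.1% on day 0 and 71.6% on day 10 lay in the first stretch of chromosome 9, far from its nearest protein-coding gene, Alkbh8. The strongest, from 3022464 to 3022623, lay 312694 bp from it. Others were on chromosome 2 (98664929 to 98665218), chromosome 12 (3109874 to 3110097) and chromosome 14 (19415731 to 19416261). Over 10 kb from any end of a protein-coding gene lay 94.2% and 92.6% of the regions of days 0 and 10. Between days 0 and 10 the log2 ratio was -0.08 (exact permutation p = 0.333).

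Setting the 2 antibodies side by side, the RUNX2 regions of day 3 lay where H3K4me3 lay. Of the 15899 regions 97.7% (95% interval 97.5 to 98.0) overlapped an H3K4me3 region of day 3, against a mean of 2.34% for random placements (one-sided permutation p = 0.000999, the smallest 1000 placements can give). Placements were uniform along chromosomes, and the RUNX2 regions of days 0 and 10 reached the same p. Of those, 59.3 and 60.5% overlapped H3K4me3 regions of their own day, so the p is not particular to day 3. Only 69 regions lay in none of the 6 H3K4me3 lists. RUNX2 peaks were found at 99.8% of genes marked in all 6 lists (10305 of 10322), such as Sox9 and Col2a1, at 95.3% of genes marked on day 3 and at 0.173% of genes unmarked in both day 3 libraries. H3K4me3 regions over 1 kb from gene ends had a RUNX2 region in 64.2% of cases, and those near gene ends in 95.1%.

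**Figure D4:**
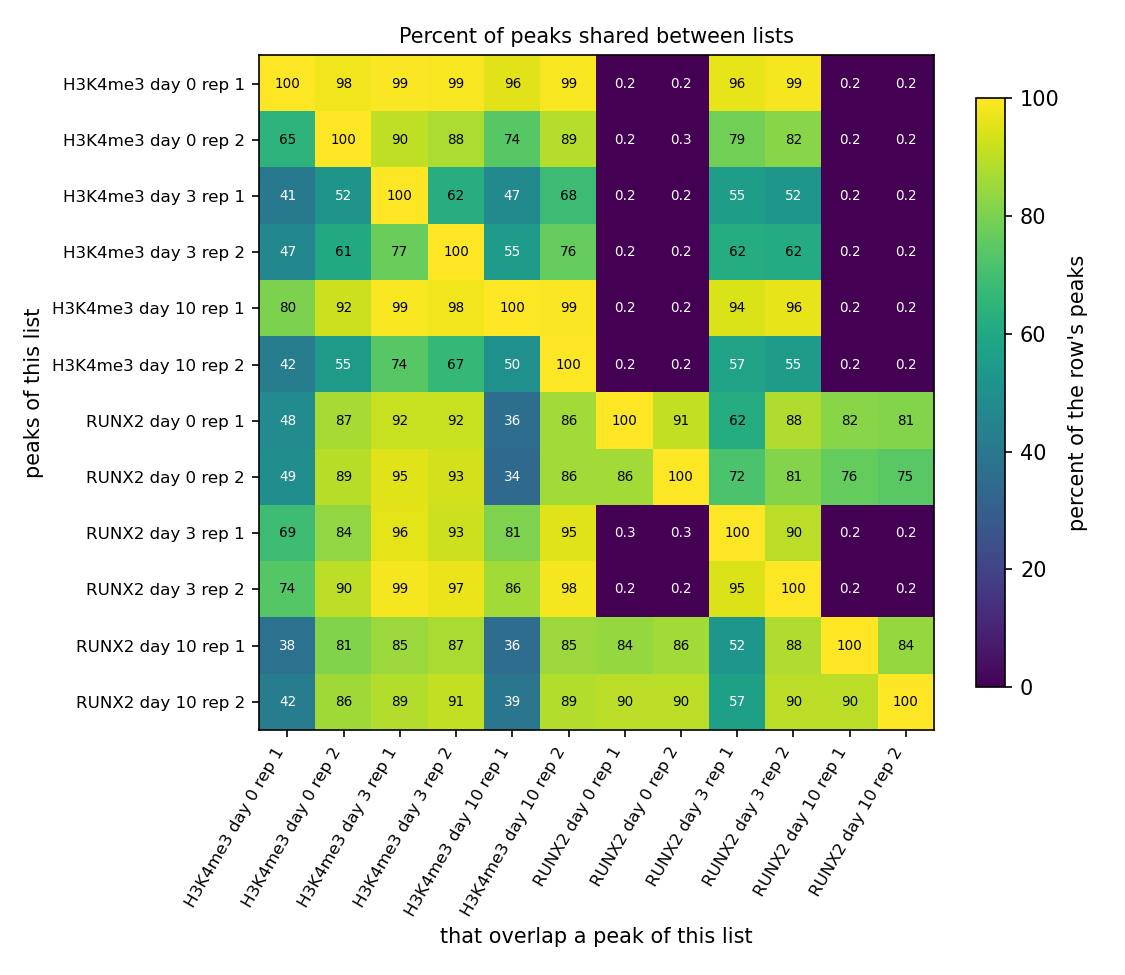
Percent of the peaks of each list (vertical axis) that overlap a peak of each other list (horizontal axis), as colour and number, for all 12 lists. The RUNX2 lists of day 3 share 69.1 to 98.7% of their peaks with the H3K4me3 lists, and those of days 0 and 10 share 74.5 to 90.7% with each other.

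Of the 560 genes that gained H3K4me3 by day 3, 248 had a RUNX2 peak in both libraries on day 3, among them Acan, Spp1, Matn4, Panx3 and Adm, against 50 of 9651 genes that did not gain one (odds ratio 152.6, Fisher's exact test, p = 8.71e-284). Nearly all of the latter were unmarked on day 3, so this ratio restates that RUNX2 peaks lie at marked genes, and the 44.3% of gained genes with RUNX2 are fewer than the 95.3% of all marked genes. Gained genes without RUNX2 in either library included Ihh, Bmp3, Hdac4, Gdf5 and Lgr6. RUNX2 was found at 75.3% of the 190 genes that kept the mark in both libraries on day 10 (95% interval 68.5 to 81.2) and at 28.4% of the other 370, with 6.25% among the 64 of these that had no peak in either library (1.73 to 15.2). It was found at 0 of the 15 gained on day 10 only, Ibsp and Dkk1 among them, which allows a share of up to 21.8%. Genes that lost H3K4me3 from day 3 to day 10 rarely had RUNX2 on day 3, 7 of 95 against 11507 of 11993 (odds ratio 0.00336, Fisher's exact test, p = 3.45e-110). Weak marking was not adjusted for: RUNX2 was also less frequent in the weakest of 4 groups of marked genes by H3K4me3 rank (83.5%) than in the strongest (99.2%). With a library left out the odds ratio for gains lay between 94.8 (without RUNX2 replicate 2 of day 3) and 291 (without H3K4me3 replicate 2 of day 0). That for losses lay between 0.00201 (without H3K4me3 replicate 1 of day 3) and 0.00710 (without H3K4me3 replicate 2 of day 10). Both odds ratios compare a RUNX2 peak with an H3K4me3 peak of the same day and gene, and genes are not independent replicates.

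**Figure D5:**
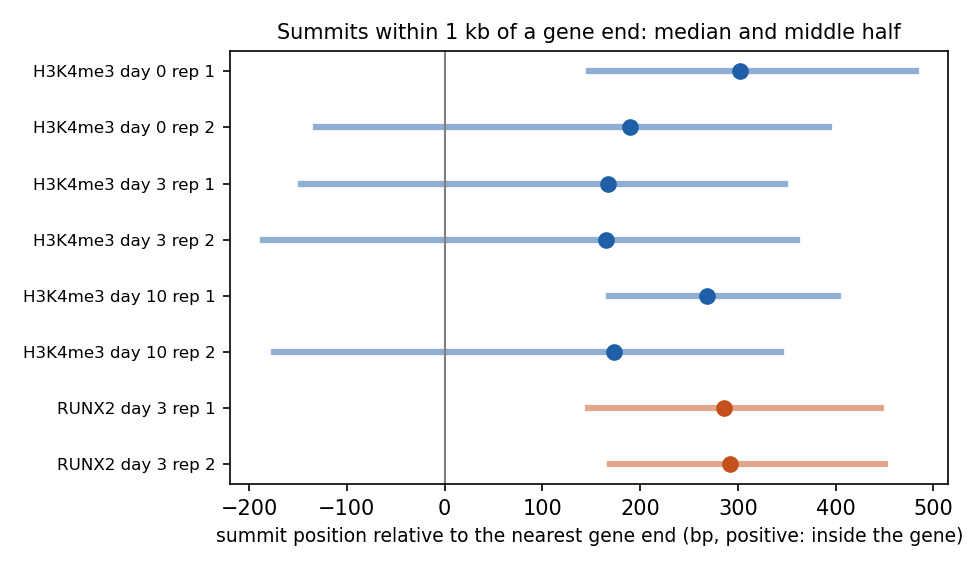
Position of peak summits relative to the nearest gene end in bp, positive inside the gene, for summits within 1 kb of a gene end in the 6 H3K4me3 lists (blue) and the RUNX2 lists of day 3 (orange), with points for medians and bars for the middle 50%. The RUNX2 medians lie at 286 and 292 bp and the H3K4me3 medians between 165 and 302 bp.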

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

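The tests that weigh the patterns below were chosen after the results had been seen.

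Peaks were also called on sequence that the comparisons leave out. On a single unplaced sequence of the assembly the H3K4me3 lists held 29 and 25 peaks on day 0, 27 and 28 on day 3 and 21 and 34 on day 10, and the RUNX2 lists held 69 and 64 on day 0, 23 and 17 on day 3 and 73 and 73 on day 10. On the mitochondrial genome the RUNX2 lists had 2 and 3 peaks on day 0, 6 and 1 on day 3 and 4 and 4 on day 10, and the H3K4me3 lists 0. The 6, 4 and 4 were flagged for exceeding 3, a counting limit for a count of 0. Called peaks are not independent counts, and no control list was used to set a level for them, so passing that limit decides nothing.

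The RUNX2 regions of day 3 lie in H3K4me3 regions at genes such as Sox9, Col2a1 and Rplp0, and the readings below were not settled. If RUNX2 sat in the nucleosome-poor stretch at gene starts, its summits should crowd the gene end. Only 3.89 and 3.71% of near-end summits lay within 100 bp of it, below the median of 8.36% in the H3K4me3 lists. The lowest H3K4me3 value, 3.91%, was close and came from replicate 1 of day 10. Its shortest peak measured 245 bp, against 254 bp in both RUNX2 lists. Gene spans without strand also do not locate gene starts, so the share does not decide that reading. A candidate explanation is that these libraries hold H3K4me3 chromatin, through a wrong label, antibody or carry-over. The median summit lay 286 and 292 bp inside the gene, within the H3K4me3 range of 165 to 302. Only replicate 1 of day 0 (302) and replicate 1 of day 10 (268) came near those values. These were the H3K4me3 lists with the longest shortest peaks, 295 and 245 bp. The other medians lay at 165 to 190 bp, so the offset does not separate this reading from fragment length. The libraries held 96.3 and 98.6% of the shortest H3K4me3 list, as the other H3K4me3 lists did (95.6 to 99.3%). That share restates the overlap to be explained, so it does not separate this reading from RUNX2 binding at marked genes. Peak width and −log10 q were also correlated (Spearman) at the 10305 genes with a peak in all these lists. RUNX2 with H3K4me3 lists gave 0.499 to 0.793 for width and 0.310 to 0.777 for −log10 q. Pairs of H3K4me3 lists gave 0.535 to 0.771 and 0.415 to 0.687, and the RUNX2 pair 0.734 and 0.705. Both highest values joined RUNX2 replicate 2 with H3K4me3 replicate 1 of day 10. Both lowest came from RUNX2 replicate 1, so the correlations do not decide this reading. They also compare ranks and not absolute widths. Peaks wider than 3 kb made up 0.0673% of RUNX2 replicate 1, below the 0.915 to 6.18% of the H3K4me3 lists, and 3.56% of replicate 2, within that range. The mitochondrial genome held 6 and 1 peaks in these RUNX2 lists and 0 in the H3K4me3 lists. The width difference rests on 1 library and the mitochondrial peaks are few, so neither decides. Whether any antibody would give peaks at marked gene starts cannot be told apart, since only 0.239% of the day 3 regions recur in the RUNX2 lists of days 0 and 10 and the depth of those lists is unknown. Their shortness limits that share. Conversely, 77 of the 86 regions of day 0 and 74 of the 81 of day 10 lay in RUNX2 regions of day 3. Binding of RUNX2 across marked promoters on day 3, a difference the design names, stays open and untested.

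The short RUNX2 lists of days 0 and 10 may hold high-copy sequence called whatever the antibody, since 97.7 and 97.5% of their regions, such as those at the start of chromosome 9, also lay in an H3K4me3 list. They do not hold the strongest of the day 3 gene-end regions, as 2.33 and 2.47% of them lay near gene ends (upper limits 8.15 and 8.64%), against 65.8% on day 3. Lower binding of RUNX2 on those days cannot be told apart from a lower depth or yield, both unknown. The libraries also differed in their shortest peak, a value that follows the fragment length the caller estimates. It measured 254 and 254 bp in the RUNX2 lists of day 3, 100 and 109 bp on day 0 and 104 and 105 bp on day 10. Runx2 itself had an H3K4me3 peak in all 4 lists of days 0 and 10, which does not measure the protein.

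The gains of H3K4me3 from day 0 to day 3, with Acan, Spp1 and Matn4 among them, were weighed against 2 technical readings. Longer day 3 lists are argued against as the whole cause, because 254 genes gained a peak with equal numbers of peaks, against 84 for the larger crosswise split, although the cartilage matrix list no longer passed there (3 of 18 members, odds ratio 8.49 in place of 11.6). Some of the 254 may have had a lower-ranked day 0 peak that the cut removed. Cartilage matrix members counted as unmarked on day 0 rose from 15 to 18. Whether the day 0 library with longer fragments, as judged by its shortest peak, contributes cannot be told apart. Without that library 602 genes gained a peak, but leaving out a day 0 library can only keep or raise that count. A difference in immunoprecipitation yield between days was not tested, and a biological change with differentiation remains a hypothesis.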

How the results depend on the processing

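Most alternatives were planned. A peak anywhere in the gene span, genes with peaks at both ends left out, the 4 H3K4me3 libraries with shorter fragments and the crossed pairing were chosen after seeing the data. Fragment length was judged by the shortest peak of a list and was not measured. Of 197 alternative values for 20 results, 142 kept their direction and stayed within the spread or within 1.5 times the count, and both odds ratios of RUNX2 with H3K4me3 change kept theirs in all 18. The cause of the changes below was not tested unless given. The search for the RUNX motif and its alternatives were not run, and unknown read depth limits every absent peak.

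With equal numbers of top peaks the gained and lost genes were 254 and 24 (day 0 to 3), 38 and 53 (3 to 10) and 16 lost (0 to 10), 2 lists passed in place of 5, and day 3 kept 26 RUNX2 regions, because the shortest RUNX2 list sets the number. With all annotated genes they were 977 and 1 (0 to 3), 167 lost (3 to 10) and 371 and 3 (0 to 10), as more genes were examined. Windows of 500 bp gave 2 lost genes from day 0 to 3 and 2 from day 0 to 10, and windows of 2500 bp gave 11 lists. A −log10 q of at least 5 gave 59 lost genes (3 to 10), 2 lists and a RUNX2 share in H3K4me3 of 97.4%. A peak anywhere in the gene span gave 2 (0 to 3) and 1 (0 to 10) lost genes and 9 lists. The shorter-fragment libraries gave 59 lost (0 to 3), 194 gained (3 to 10), 938 gained and 110 lost (0 to 10), 8 lists and a log2 ratio of 0.0664 for day 10 against 3, the opposite direction. Peaks on all sequences gave 0.0121 for RUNX2 on day 10 against 0, also opposite. An overlap of 50% in both directions gave a share of 87.5%, leaving out regions in all 6 H3K4me3 lists kept 3923 RUNX2 regions, and a background of marked genes left 1 RUNX2 list in place of 27.

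Leaving out each library in turn gave log2 ratios of H3K4me3 peak number of 0.41 to 1.01 (day 3 against 0), -0.86 to 0.0664 (10 against 3) and -0.19 to 0.75 (10 against 0). Gained and lost genes ranged from 602 to 1677 and 0 to 59 (0 to 3), 20 to 194 and 99 to 828 (3 to 10), and 261 to 954 and 0 to 108 (0 to 10), 6 to 16 lists passed, and the RUNX2 share was 92.5 to 99.1%. The highest values came without replicate 2 of day 0 (1677 and 954), replicate 1 of day 0 (59 and 108), replicate 1 of day 10 (194) and replicate 2 of day 10 (828 and 16). A call that needs both libraries is kept by construction when 1 is left out. Of 41 genes named for day 0 to 3, 19 were called with equal numbers, 23 with 2500 bp and 25 with 500 bp. Of 13 named gains from day 3 to 10, 0 were called with equal numbers, of 14 named losses 4 with 500 bp and 5 with 2500 bp, and of 28 gains from day 0 to 10, 17 with equal numbers. None reversed. The replicate numbers were not taken to pair the samples. The correlation of deviations was positive only for days 0 and 10 (-0.0001, -0.15 and 0.30), where replicate 1 of both days had longer fragments as judged by the shortest peak. With the replicate number as a block the H3K4me3 log2 ratios were 0.71, -0.40 and 0.31 and those of RUNX2 7.43, -7.51 and -0.08, with no change of direction, and crossing the numbers for day 10 against 3 also gave -0.40, since a mean of log ratios does not depend on the pairing.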

Other observations

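The matched test of RUNX2 by list, the pairing of the H3K4me3 lists and the widths below were chosen after the results had been seen.

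The widest single H3K4me3 peak at key chondrocyte genes was wider on day 3 than on day 0 in both libraries. This is not the width of a domain, since the caller can divide a domain: Col2a1 and Sp7 each had 3 peaks in replicate 1 of day 0. The widest peak within Runx2 measured 3720 and 7503 bp on day 0, 10850 and 8958 bp on day 3 (chromosome 17, 44728702 to 44739551 in replicate 1) and 4869 and 8900 bp on day 10. At Sox9 the values were 3608 and 3786, 7314 and 5890, and 4897 and 6373 bp, and at Col2a1 they were 913 and 1647, 5130 and 4958, and 3288 and 4716 bp. Sp7 went from 2099 and 5161 bp on day 0 to 6559 and 5511 bp on day 3, and Alpl from 941 and 2404 to 3493 and 2506 bp. Peaks wider than 3 kb made up 0.915 and 1.98% of the day 0 lists, 6.18 and 2.80% of the day 3 lists and 1.50 and 4.01% of the day 10 lists, while the median width was 945 and 852 bp on day 0 and 936 and 794 bp on day 3. Whether these genes widened more than others was not tested.

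Lists for other lineages differed in how many genes were marked. A peak in both libraries was found at 1 of 20 skeletal muscle genes on each day, at 3, 5 and 4 of 23 pluripotency genes on days 0, 3 and 10, and at 1, 5 and 3 of 23 haematopoietic genes. Epithelial genes had 1, 8 and 2 of 21, with 7 already marked in replicate 2 of day 0 and 9 in replicate 2 of day 10. Tendon and fibroblast genes had 12, 15 and 10 of 25, adipocyte genes 8, 10 and 9 of 20, and limb patterning genes 17, 30 and 23 of 40. RUNX2 on day 3 was found at 99.2% of genes in the strongest of 4 groups by H3K4me3 rank and at 83.5% in the weakest. Against genes matched on that rank, 20 of 30 marked limb patterning genes with RUNX2 compared with 23.9 in 10000 random lists (95% range 21 to 27, two-sided p = 0.0240 by permutation, adjusted p = 0.408 over 17 lists), so their lower share did not pass. Alx4, Barx1, Barx2, Dlx3, Foxc1, Hand2, Hoxd11, Pitx1, Prrx1 and Tbx15 were those without it.

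Of the 15 ways to pair the 6 H3K4me3 lists, pairing them by day gave 269 genes whose pairs were alike within and different between. Of the other ways, 4 gave more: the 3 that join replicate 1 of day 0 with replicate 1 of day 10 (428, 452 and 536), and 1 that keeps day 0 together and mixes days 3 and 10 (340). This points to a structure of the libraries beside the days.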
